A study of Coturnix japonica with 4 samples.

How the data were processed

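Embryonic skin of Japanese quail (Coturnix japonica) was profiled by RNA sequencing at embryonic day 7. Per the labels, skin was cut from the black and the yellow stripes, 2 libraries were made per stripe, and each library pooled tissue of 4 embryos. RNA was extracted with Trizol, libraries were made with an Illumina TruSeq kit and sequencing was done on an Illumina NextSeq instrument, per the labels. The submitters' processing notes name TopHat2 2.1.1, a spliced read aligner, and Cufflinks 2.2, a transcript quantifier that also compares groups. The genome build, the annotation, the strand setting and the step that combined the 2 libraries of a group are not given in the sources used here.

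The tables hold RPKM values (reads per kilobase of transcript, scaled to the number of mapped reads) that the authors computed, with 1 value for each stripe, as the column names of the deposited table show. Values per library were not used here, so no replicate spread, standard error or test of separate libraries could be computed, and group values are given without SD or n. The authors' p-values and false discovery rate (q-value) per gene come from a deposited sheet exported from a QIAGEN program, per the file headers. The authors' log2 ratios in that sheet are black over yellow. They lay within 0.01 of the log2 ratio of the named RPKM columns in all 10503 genes with at least 0.5 RPKM in both stripes. The p-values of the 2 sheets were identical in all genes. A further column of the deposited table marks 366 genes, which were exactly those with an unadjusted p under 0.05.

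The table has 12419 rows. Rows were identified by the authors' gene ID. In 11 rows a spreadsheet had turned the ID into a date number, and the QIAGEN program had then given those rows the symbols of unrelated genes, so they were left out. A further 25 rows shared 4 repeated transfer RNA IDs, were all listed at 0 RPKM, and were left out too. This left 12383 genes, of which 11844 carry a symbol of the RefSeq annotation of Coturnix japonica 2.1. That assembly was used for names and for which genes are neighbours. No coordinates are given because the build of the deposited values is not stated. Read totals per library are not in the values, so the depth behind each value is unknown. The 452 genes between 0 and 0.1 RPKM in both stripes had 194 different ratios, the most frequent in 8 genes, so low values showed no common step from which depth could be read.

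Log2 ratios of black over yellow were computed from the RPKM values without a pseudocount. A gene was called different where the authors' q-value was under 0.05. No test was run on the values themselves, as planned for tables with 1 value per group. The deposited sheets give no test status, so the 10569 genes with p under 1 were taken as tested. The lowest p in the table was 5e-05, reached by 30 genes, and it gave the lowest q of 0.0177. How the 2 libraries of a stripe entered these p-values is not given in the sources used here.

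The 25 gene lists, the threshold and the rule for named genes were fixed before the data were examined. List members were counted as measured at a mean of at least 1 RPKM. For each list the text gives the members past the threshold over all genes. It also gives the number past 0.05 when the authors' p-values were adjusted over the list alone (Benjamini-Hochberg). The list's median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from 10061 measured genes and matched in 20 bins of mean expression. This percentile describes these group values and is not a p-value, since genes of a list vary together. A list was said to stand apart below the percentile of 2.5 or above that of 97.5, limits chosen after the data were seen. In simulated data with independent genes and normal log2 ratios of the measured SD of 0.25, the procedure set apart 1 of 40 unshifted lists of 8 genes. Of 40 unshifted lists of 26 genes it set apart 0. It set apart 29 of 40 lists of 8 genes and 39 of 40 of 26 genes that were shifted by 1 SD. Smaller shifts were not simulated. The simulation left out that genes of a list vary together and the shape of the measured ratios, whose quartiles were -0.08 and 0.08. These counts therefore give no error rate for the fixed lists.

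The rule for named genes takes the 10 genes with the largest log2 ratio in each direction past the threshold, with at least 1 RPKM in the higher stripe and a symbol. It adds up to 6 members of each list past the threshold, the 3 most abundant members not past it for the lists of melanin synthesis, melanocyte regulators, agouti axis, connexins and feather buds, and the 3 most abundant genes listed at 0 in 1 stripe. Members past 0.05 adjusted over the list alone, and further genes given for comparison, were chosen after their values were seen. The text leaves out 1 gene that the rule takes, which is not used here. Alternatives covered other floors on RPKM, stricter and looser thresholds, pseudocounts, scaling of the 2 stripes, random lists without matching, and p-values adjusted again. Leaving out single libraries and a replicate block could not be run on 1 value per stripe. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.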

Results

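The data compare skin of the black and the yellow longitudinal stripes of Japanese quail embryos at day 7, with 2 libraries per stripe and 4 embryos pooled in each library. The comparison asks which genes differ in expression between the stripes. Only 1 RPKM value per stripe was analysed, named E7B and E7Y in the table. They are called the black-labelled and the yellow-labelled value throughout, because the pigment genes described next run against these names. Of 12383 genes, 10072 reached 1 RPKM in the black-labelled value and 10037 in the yellow-labelled value. The 2 values were close for most genes. Across the 10061 genes with a mean of at least 1 RPKM, Pearson's r of log2(RPKM + 1) was 0.993, where genes are not independent replicates, and the log2 ratio had a median of -0.00 and an SD of 0.25. The depth behind the values is unknown, and no replicate error can be given.

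In the authors' deposited table, 35 genes had a q-value under 0.05, 18 of them higher in the black-labelled and 17 higher in the yellow-labelled value. An unadjusted p under 0.05 was reached there by 366 genes. The largest ratios among the 35 belonged to melanosome genes, which were higher in the yellow-labelled value. TYRP1, a melanosomal enzyme of eumelanin synthesis, had 68.2 RPKM in the yellow-labelled and 2.71 RPKM in the black-labelled value, a 25.2-fold ratio. TYR, the rate-limiting enzyme of melanin synthesis, was 12.3-fold higher in the yellow-labelled value, and DCT, which acts next to it, was 6.76-fold higher. In the other direction, PITX1, a homeobox regulator of hindlimb identity, was 6.59-fold higher in the black-labelled value and APOA1, a lipoprotein component, was 6.24-fold higher. Each of these 5 genes had q = 0.0177 in the authors' deposited table, the lowest value its p-values allow.

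**Figure D1:**
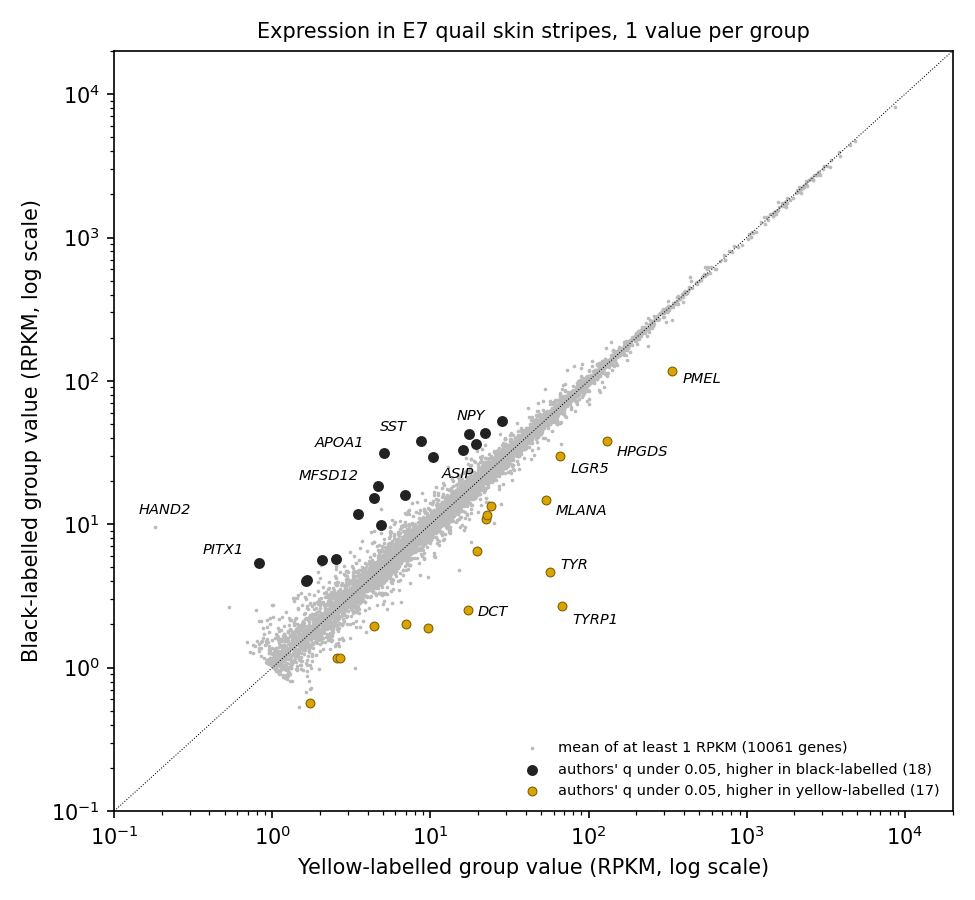
Each point is a gene, with the yellow-labelled group value on the x axis and the black-labelled group value on the y axis, both in RPKM on log scales; the dotted line marks equal values. Grey points are the 10061 genes with a mean of at least 1 RPKM (APOH, at 0.05 RPKM in the black-labelled value, falls below the axis), dark points the 18 and yellow points the 17 genes with an authors' q-value under 0.05, and TYRP1 and TYR lie farthest below the line among the latter.

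Of 26 measured members of the melanin synthesis and melanosome list, 5 were past the threshold, all higher in the yellow-labelled value, and 0 were past it in the other direction. Beside TYRP1, TYR and DCT, these were PMEL, the fibril protein of the melanosome, at 336 against 118 RPKM (2.85-fold), and MLANA, a melanosome protein, at 53.5 against 14.7 RPKM (3.63-fold). All 5 had q = 0.0177 in the authors' deposited table. When adjusted over the list alone, 7 members passed, all higher in the yellow-labelled value, adding OCA2 (1.48 against 0.53 RPKM) and SLC24A4 (2.65 against 1.41 RPKM). The list's median log2 ratio of black over yellow was -0.25, below every one of the random lists. It was -0.14 with members down to a mean of 0.1 RPKM and -0.14 at a floor of 5 RPKM, again below every random list. Epidermal and smooth muscle markers, described further on, also had negative medians, of -0.15 and -0.20. The remaining 21 members were not past the threshold. Among them GPNMB had 116 RPKM in the yellow-labelled and 86.0 RPKM in the black-labelled value, MLPH 32.8 and 20.2 RPKM, and WIPI1 85.0 and 89.3 RPKM. SLC45A2, a melanosome transporter, had 7.31 RPKM in the yellow-labelled and 9.15 RPKM in the black-labelled value.

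Of 15 measured transcription factors, receptors and other regulators of the melanocyte lineage, 0 were past the threshold, and 0 passed adjusted over the list alone. At unadjusted p under 0.05 the authors' deposited table has 1 member higher in each direction. MITF, the master regulator of melanocytes, had a log2 ratio of black over yellow of -0.25. SOX10, a neural crest regulator, had 22.4 RPKM in the black-labelled and 25.2 RPKM in the yellow-labelled value, KIT, the receptor of stem cell factor, 30.8 and 23.6 RPKM, and PAX3 6.89 and 5.75 RPKM. The most abundant members were SNAI2 with 215 RPKM in the black-labelled and 201 RPKM in the yellow-labelled value, ZEB2 with 118 and 110 RPKM, and CDK2 with 74.2 and 100 RPKM. CDK2 is the direct neighbour of PMEL in Coturnix japonica 2.1, and whether reads were counted by strand is not stated. The list median was 0.07, at percentile 97.6 of random lists, and it no longer stood apart at a floor of 5 RPKM or against unmatched lists.

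Of the agouti and melanocortin axis, ASIP was the member past the threshold among 8 measured. ASIP, the agouti signal that turns melanocytes toward yellow pigment, had 29.4 RPKM in the black-labelled and 10.4 RPKM in the yellow-labelled value. The ratio was 2.83-fold, with q = 0.0438 in the authors' deposited table. PCSK2, a prohormone convertase, had 3.43 RPKM in the black-labelled and 5.66 RPKM in the yellow-labelled value and passed when adjusted over the list alone, as did ASIP. The list's median of -0.04 and mean of 0.07 differed in sign, and the list did not stand apart. The median was -0.13 with members down to 0.1 RPKM. MGRN1 (68.9 and 75.4 RPKM), ATRN (17.3 and 18.1 RPKM) and SLC7A11 (16.3 and 16.4 RPKM), the cystine transporter tied to yellow pigment, were not past the threshold. MFSD12, a lysosomal and melanosomal transporter, was 3.97-fold higher in the black-labelled value, at 18.4 against 4.64 RPKM, with q = 0.0177 in the authors' deposited table.

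**Figure D2:**
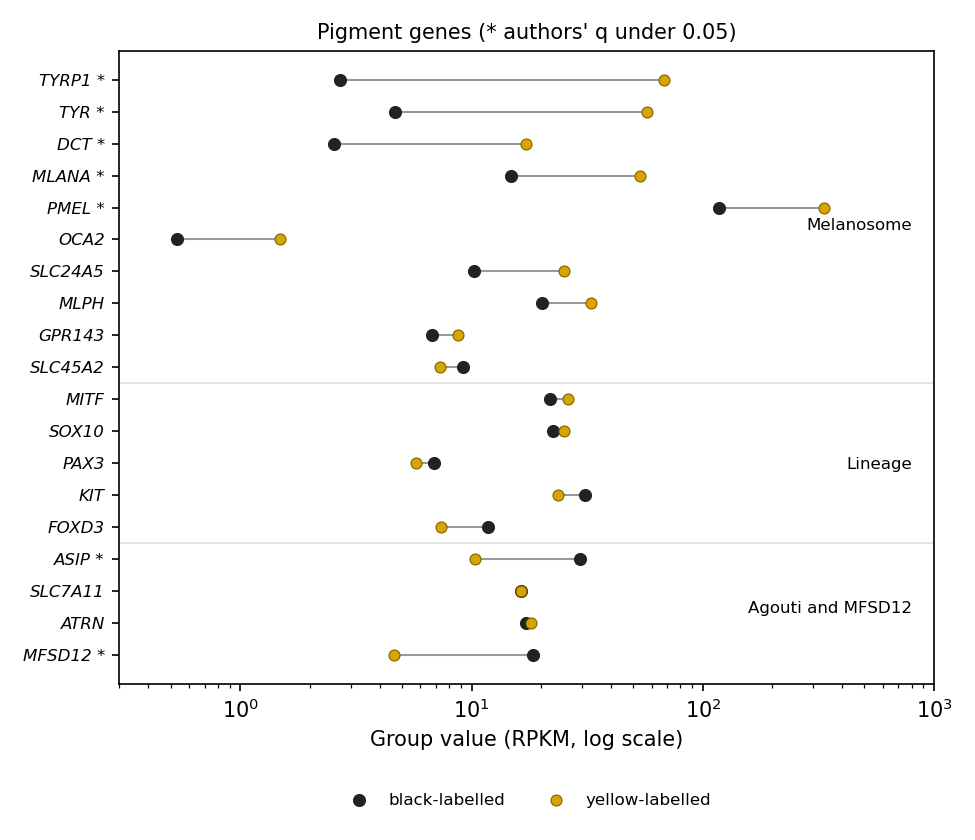
Group values in RPKM (log x axis) of pigment genes, with dark points for the black-labelled and yellow points for the yellow-labelled value and an asterisk where the authors' q-value was under 0.05. TYRP1, TYR, DCT, MLANA and PMEL are higher in the yellow-labelled value, ASIP and MFSD12 are higher in the black-labelled value, and the values of MITF and SOX10 lie close together.

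None of the 18 measured ligands of melanocyte receptors and guidance factors was past the threshold. Of these, 3 passed adjusted over the list alone, and the list median of 0.00 did not stand apart. DKK1, a Wnt antagonist, had 29.2 RPKM in the black-labelled and 16.8 RPKM in the yellow-labelled value. KITLG, the stem cell factor, had 15.1 and 22.4 RPKM, and EDN2, an endothelin, 6.02 and 10.5 RPKM. Connexins and pannexins, which form intercellular channels, had 7 measured members and 0 past either threshold. GJA1 had 494 RPKM in the black-labelled and 445 RPKM in the yellow-labelled value, GJA5 73.4 and 72.7 RPKM, and GJC1 13.8 and 16.9 RPKM. The list median was 0.03, and its direction depended on the floor, at -0.07 with members down to 0.1 RPKM and 0.11 at a floor of 5 RPKM. Of 12 measured potassium channel and polyamine genes, 0 passed over all genes. The 1 that passed adjusted over the list alone was ODC1, the first enzyme of polyamine synthesis, with 128 RPKM in the black-labelled and 80.8 RPKM in the yellow-labelled value. This list's median of -0.16, at percentile 0.15, lay in the direction opposite to ODC1. It became -0.11 with a pseudocount of 1 and 0.04 at a floor of 5 RPKM.

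Of 31 measured feather bud and placode genes, 0 were past the threshold over all genes, and 4 passed adjusted over the list alone. DLL1, a Notch ligand, had 16.4 RPKM in the black-labelled and 8.87 RPKM in the yellow-labelled value. FGF10 had 7.55 and 4.37 RPKM, and FGF20, a placode signal, had a log2 ratio of 1.34. TNC, a matrix protein, had 24.3 and 36.2 RPKM. The abundant members LEF1 (143 and 127 RPKM), FGFR2 (130 and 143 RPKM) and WNT11 (108 and 131 RPKM) were not past either threshold. The list median was 0.07, at percentile 99.8. Of 32 measured Wnt ligands and targets, 1 was past the threshold in each direction. WIF1, a secreted Wnt inhibitor, was 1.94-fold higher in the black-labelled value, at 43.0 against 22.2 RPKM. LGR5, a receptor of R-spondins, was 2.21-fold higher in the yellow-labelled value, reaching 66.2 RPKM. Both had q = 0.0177 in the authors' deposited table. Of the Wnt list 5 passed adjusted over the list alone, with DKK1 and RSPO2 (6.88 against 3.58 RPKM) also higher in the black-labelled value and WNT2 (11.4 against 7.13 RPKM) in the yellow-labelled value. The Wnt list median was 0.08, at percentile 99.95.

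The list fixed under the name of mediolateral patterning of the trunk stood apart, with a median log2 ratio of 0.31 over 16 measured members, above every one of the random lists. It also holds regulators of the limb, so its name does not tell which body axis a difference follows. PITX1 was the 1 member past the threshold over all genes, at 5.39 against 0.82 RPKM. With p-values adjusted over the list alone, 7 members passed that were higher in the black-labelled and 2 in the yellow-labelled value. HAND2, a regulator of the posterior limb bud and heart, had 9.64 RPKM in the black-labelled and 0.18 RPKM in the yellow-labelled value, with q = 0.0634 in the authors' deposited table. EN1 had 8.82 and 4.18 RPKM, ZIC1 19.5 and 12.1 RPKM, TBX18 10.6 and 6.45 RPKM, ALX4 7.84 and 5.05 RPKM, and SIM1 4.23 and 2.51 RPKM. TBX2, with 0.72 and 1.75 RPKM, and LMX1B, with 29.0 and 38.8 RPKM, passed in the other direction. Cartilage (0.18), skeletal muscle (0.16) and neuronal markers (0.28), described further on, also had positive medians. With members down to a mean of 0.1 RPKM included, the list median was 0.04 and did not stand apart, and at a floor of 5 RPKM it was 0.08. Of 27 measured HOX genes, 0 passed over all genes and 0 over the list alone. Their median was -0.07, at percentile 1.35, and at a floor of 0.1 RPKM the list no longer stood apart. The 3 HOX genes with an unadjusted p under 0.05 in the authors' deposited table were higher in the yellow-labelled value. They were HOXB2 (3.92 against 1.78 RPKM), HOXB4 (18.1 against 7.56 RPKM) and HOXC8 (20.8 against 13.7 RPKM).

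Smooth muscle and pericyte genes had a median log2 ratio of -0.20 over 11 members, at percentile 0.115, and of -0.46 over the 5 members left at a floor of 5 RPKM. MYH11, the smooth muscle myosin heavy chain, was 3.49-fold higher in the yellow-labelled value, at 6.97 against 2.00 RPKM, with q = 0.0177 in the authors' deposited table. Adjusted over the list alone ACTA2 (28.6 against 19.1 RPKM) passed in the same direction and DES (1.36 against 2.94 RPKM) in the other. Epidermal keratinocyte genes had a median of -0.15 over 17 members, at percentile 0.005, with 14 members higher in the yellow-labelled value and 0 past either threshold. KRT18 was the 1 keratin measured among them, with a log2 ratio of 0.66. Proliferation genes had a median of 0.11 over 27 members, above every one of the random lists, with 21 members higher in the black-labelled value and 0 past either threshold.

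Skeletal muscle genes had 8 measured members and 0 past the threshold. Adjusted over the list alone, TNNC1 (log2 ratio 0.95), PAX7 (4.25 against 2.01 RPKM) and DES, which is also on the smooth muscle list, passed, higher in the black-labelled value. Their median was 0.16, at percentile 91.7 (99.7 against random lists that were not matched, where it stood apart), and became 0.04 with members down to 0.1 RPKM and 0.09 with a pseudocount of 1. Cartilage and bone genes had a median of 0.18 over 11 members, at percentile 99.1, and 1 of them passed over the list alone, COL2A1, at 64.6 RPKM in the black-labelled and 41.6 RPKM in the yellow-labelled value. With members down to 0.1 RPKM the median was 0.07 and did not stand apart, and at a floor of 5 RPKM it was 0.29. Neuronal genes had a median of 0.28 over 8 members, at percentile 99.6. It was 0.12 at a floor of 0.1 RPKM and -0.02 at one of 5 RPKM, and stood apart at neither. Adjusted over the list alone, TUBB3 (10.4 against 5.99 RPKM) was higher in the black-labelled value, and ELAVL4 (6.41 against 4.07 RPKM) and GAP43 (4.99 against 2.79 RPKM) were higher in the yellow-labelled value.

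Of dermal fibroblast, endothelial, Schwann cell, immune, fat cell, red blood cell, immediate early and housekeeping genes, 0 were past either threshold and none of these lists stood apart from matched random lists. Their medians were 0.03 over 28 fibroblast, 0.04 over 18 endothelial, 0.07 over 9 Schwann cell, 0.15 over 7 immune, -0.04 over 9 fat cell and -0.15 over 3 red blood cell members. They were 0.03 over 22 immediate early and -0.00 over 18 housekeeping members. The mean differed in sign from the median for endothelial, Schwann cell and housekeeping genes. At a floor of 5 RPKM the Schwann cell list stood apart with a median of -0.16, and the immune median was 0.02. Against random lists that were not matched the immune list stood apart, at percentile 99.0. The red blood cell median was -0.10 with a pseudocount of 1. The 12 W chromosome genes fixed as markers of female embryos were not analysed here.

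**Figure D3:**
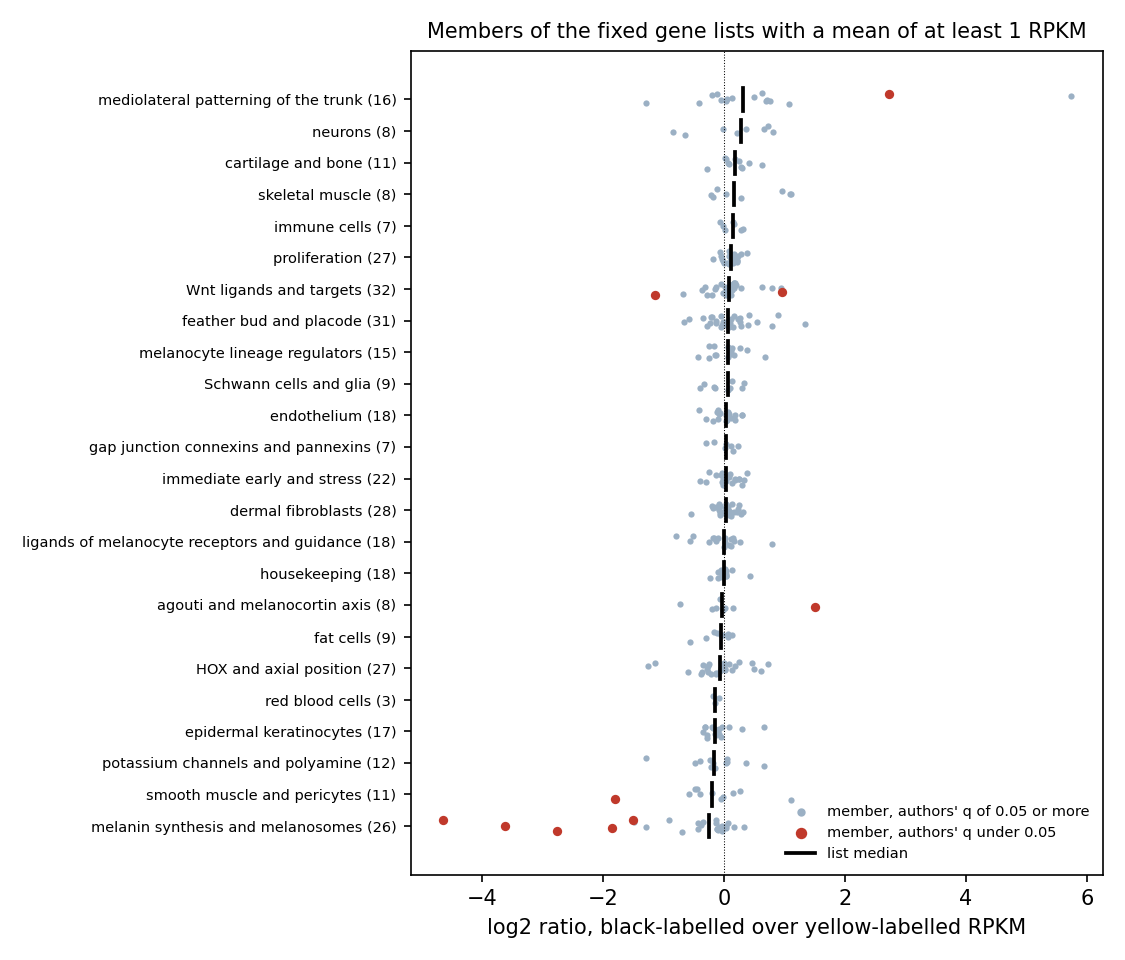
Log2 ratio of the black-labelled over the yellow-labelled RPKM for each measured member of the fixed lists (x axis), by list with its number of measured members (y axis), ordered by list median (bars); jitter within a list is for display. Red points are members with an authors' q-value under 0.05, and they sit far to the left in the melanosome list, where the median is -0.25.

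Further genes with large ratios belonged to no fixed list. Higher in the black-labelled value were the neuropeptide SST (38.1 against 8.77 RPKM, 4.35-fold), CYTL1 (15.2 against 4.39 RPKM, 3.47-fold) and the transporter SLC4A11 (11.7 against 3.46 RPKM, 3.39-fold). CHRDL1, a bone morphogenetic protein antagonist, was 2.73-fold higher (5.64 against 2.07 RPKM), SHISA6 2.45-fold (4.05 against 1.65 RPKM) and the growth factor IGF1 2.44-fold (4.01 against 1.64 RPKM). Higher in the yellow-labelled value was HPGDS, a prostaglandin D synthase (130 against 38.1 RPKM, 3.42-fold). RAPGEF4 was 3.07-fold higher (1.73 against 0.56 RPKM), and MGP, an inhibitor of calcification, 3.05-fold (19.7 against 6.46 RPKM). Each of these 9 genes had q = 0.0177 in the authors' deposited table. The most abundant genes listed at 0 in 1 stripe were all low. ATP1B2 had 0.36 RPKM and RPRML 0.29 RPKM in the black-labelled value alone, and GOLT1A had 0.13 RPKM in the yellow-labelled value alone.

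Of 79 measured genes at least 2-fold apart, 30 had a q-value under 0.05 in the authors' deposited table, and the smallest ratio among the 35 genes was 1.82-fold, for EML1.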

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

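The adjustment of p-values again, over tested genes and over genes with a mean of at least 1 RPKM, was chosen after the data were seen; the other alternatives were planned. The count of 35 genes, 18 higher in the black-labelled and 17 in the yellow-labelled value, moved by over 1.5 times under 2 thresholds only. At q under 0.01 it was 0, 0 and 0, because the lowest p of 5e-05 gave no q below 0.0177. With the authors' mark, unadjusted p under 0.05, it was 366 genes, 219 and 147. A mean of at least 5 RPKM left 25 genes and a ratio of at least 2-fold left 30. The same 35 genes passed when p-values were adjusted again in either way. This says little about stability. Adjusting over tested genes may only repeat how the authors' q-values were made, which is not stated. Adjusting over genes with a mean of at least 1 RPKM could add calls but not lose any, since the lowest mean among the 35 genes was 1.15 RPKM. Pseudocounts and scaling cannot alter a call made on the authors' q-value, a pseudocount cannot turn a ratio, and the scalings moved all ratios by only -0.00 (median) and 0.01 (upper quartile) on the log2 scale, so these say nothing about stability. The number of lists standing apart, 12 of 24, stayed within 1.5 times under 5 alternatives. Of the 24 lists, 4 no longer stood apart with members down to 0.1 RPKM. At 5 RPKM 22 lists kept enough members, skeletal muscle and red blood cells did not, and 3 no longer stood apart while the Schwann cell list newly did. Against unmatched lists the lineage list no longer did, and skeletal muscle (percentile 99.7) and immune cells (99.0) newly did; the cause was not tested. None passed to the opposite end where a value was had. No paired analysis was possible because the values analysed give 1 number per stripe, and for the same reason no library could be left out, no other split of the libraries was made, and count models and set tests with an estimated correlation were not run. No test of separate libraries was run, so no overlap of calls was computed. Without a test status in the values, the planned use of all genes with a q-value gave the same count of 35. Depth limits are unknown for these values.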

Other observations

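All tests in this part were chosen after the results were seen. The rule for named genes left out 13 of the 35 genes with a q-value under 0.05 in the authors' deposited table, and they are named here after their values were seen. Higher in the black-labelled value were NPY, a neuropeptide (42.5 against 17.6 RPKM), CPE, a carboxypeptidase that processes neuropeptides (36.6 against 19.3 RPKM), OLFM4 (52.1 against 28.4 RPKM) and ZPLD1 (32.9 against 16.1 RPKM). SCUBE2, a secreted protein that helps release Hedgehog ligands, had 16.1 against 6.93 RPKM, CLSTN2 9.95 against 4.90 RPKM and TMTC1 5.71 against 2.53 RPKM. Higher in the yellow-labelled value were EML1 (24.2 against 13.4 RPKM), SPON1, a matrix protein (22.8 against 11.7 RPKM), and PTPRZ1, a receptor phosphatase (22.5 against 10.8 RPKM). ANKH, a pyrophosphate exporter, had 4.42 against 1.97 RPKM, SYT13 2.68 against 1.16 RPKM and MYO5C 2.56 against 1.18 RPKM. APOH had the lowest ratio of all measured genes, with 0.05 RPKM in the black-labelled and 4.96 RPKM in the yellow-labelled value, but q = 0.259 in the authors' deposited table.

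The melanosome genes were higher and ASIP lower in the value labelled yellow, the reverse of what the stripe names and the textbook roles of these genes would lead one to look for. A different scaling is not tested by the median log2 ratio of -0.00050 over 10061 genes, because RPKM values are already scaled to mapped reads. A scaling factor shifts every log2 ratio by the same amount. On its own, such a factor cannot make melanosome genes higher and ASIP lower in the yellow-labelled value. Scaling as the whole cause is thus argued against. More epidermis as the whole cause is argued against by the lower quartile of -0.27 (SD 0.25) of 17 epidermal genes. The most abundant of them was EPCAM at 111 against 126 RPKM. PMEL, the nearest to 0 of the 5 called melanosome genes, was at -1.51. More smooth muscle is argued against for TYRP1, TYR and DCT, which were at -2.76 or beyond. The lower quartile of its 11 genes was -0.47 (SD 0.71). For MLANA (-1.86) and PMEL it is also argued against as the whole cause, since that quartile stayed nearer 0 than both by more than the SD. MYH11 at -1.80 was the 1 member that reached the ratio of PMEL, and it stayed short of MLANA. TAGLN (-0.03), RGS5 (-0.05), ABCC9 (-0.20) and MYOCD (-0.46) had lower black-labelled values than MLANA and much smaller ratios. More smooth muscle as a part of the cause is not decided. Of the 11 genes, 8 were higher in the yellow-labelled value and 3 in the black-labelled value, DES (1.11), CSPG4 (0.26) and PDGFRB. PDGFRB, the most abundant, had 33.6 RPKM in the black-labelled and 30.4 RPKM in the yellow-labelled value. A different number of melanocytes as the whole cause is argued against for the 5 called melanosome genes, as far as only melanocytes make them. A change in number alone would shift such genes by the same factor. Their log2 ratios instead ran from PMEL at -1.51 to TYRP1 at -4.65, with an SD of 0.25 over all measured genes. As a part of the cause, a different number of melanocytes is not decided by these values. The lower quartile of the 15 lineage regulators was -0.163 (SD 0.28), and the farthest was CDK2 at -0.43. Some regulators are also expressed by other cells, so their ratios can stay near 0 whatever the number of melanocytes. Among melanosome genes, GPNMB (-0.44), RAB38 (-0.44), GPR143 (-0.38), TRPM1 (-0.35) and SLC45A2 (0.32) lay far from PMEL. OCA2 (-1.48) and SLC24A5 (-1.29) lay near PMEL, and SLC24A4 (-0.91) and MLPH (-0.69) lay between. An exchange of the 2 group names in the table is a candidate explanation, and of the other 21 measured melanosome list members 16 were also higher in the yellow-labelled value, but it cannot be told apart from a real difference in the labelled direction, because an exchange flips every ratio alike and no list holds a marker of stripe identity that is not a pigment gene.

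PITX1, past the threshold, and HAND2, TBX18, EN1, SIM1, ALX4 and ZIC1, past it only when adjusted over the list alone, had higher black-labelled values, as did some muscle and cartilage markers, while TBX2 and LMX1B lay the other way and the HOX median was -0.07. For PITX1 (2.72) and HAND2 (5.73), the upper quartiles of the log2 ratios were lower, 0.98 (SD 0.59) over 8 muscle genes and 0.29 (SD 0.24) over 11 cartilage genes. The most abundant of them were TNNC1 at a log2 ratio of 0.95 and COL11A1 at 70.3 against 59.2 RPKM. All these markers had higher yellow-labelled values than HAND2 (0.18 RPKM) and PITX1 (0.82 RPKM), with TNNT3 the lowest at 1.15 RPKM. This largely follows from the floor of a mean of at least 1 RPKM set for the markers. A little added tissue can raise PITX1 and HAND2 by more than such markers. With members down to 0.1 RPKM the median was 0.04 over 13 muscle and 0.07 over 16 cartilage genes. Those medians still include the more abundant markers. Muscle or cartilage left on the skin is therefore not decided for these 2 genes. Cartilage is argued against for EN1, at a log2 ratio of 1.08 and 4.18 RPKM in the yellow-labelled value. COL9A1 (0.28), COL9A2 (0.07), COL9A3 (0.08), HAPLN1 (0.01) and SPP1 (0.04) had lower yellow-labelled values than EN1 and still smaller ratios. The same markers had lower yellow-labelled values than TBX18, ALX4 and ZIC1, and COL9A1 and COL9A3 than SIM1, again with smaller ratios. Cartilage is still not argued against for TBX18, SIM1, ALX4 and ZIC1 (0.63 to 0.75). COL2A1 was at 0.63, and 10 of the 11 cartilage genes were higher in the black-labelled value. For these 4 genes cartilage and muscle, and for EN1 muscle, cannot be told apart from skin of a different body position. DES, also on the smooth muscle list, and PAX7 were at 1.11 and 1.08. Of the 8 muscle genes 3 lay the other way, ACTA1 (-0.22), TNNC2 (-0.18) and NEB (-0.12). The muscle median was 0.16, and 15 further muscle genes were under 1 RPKM. A difference in the position of the dissected stripes along or across the trunk stays open and untested for all of these genes.

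Fewer genes had a small p-value than chance gives with no difference at all. Of 10569 tested genes, 3.46% had p under 0.05 in the authors' deposited table, where 5% is expected, and 21.3% had p over 0.9, where 10% is expected. Both values are consistent with a conservative test, in which the 35 calls may understate the differences; genes are not independent, and the values of single libraries that would decide it were not analysed here.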
